A study of Mus musculus with 18 samples.

How the data were processed

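RNA sequencing counts were analysed for dorsal root ganglia of wild-type (WT) mice and of mice lacking importin alpha3 (KO), taken without injury (naive), 7 d after spared nerve injury (SNI) or 2.5 months after SNI. SNI is a model of neuropathic pain in which branches of the sciatic nerve are cut while another is left intact. The 18 libraries comprised 4 naive WT, 4 naive KO, 3 WT and 3 KO at 7 d, 1 WT and 3 KO at 2.5 months. Library numbers came from the sample titles, and genotype and time after injury from the sample characteristics. Library numbers were not shared between groups, so libraries could not be paired. No group was labelled as operated on without nerve injury, and age was not among the label items used here. Differences from naive mice may therefore include effects of surgery or age. Whether each library came from a separate animal was taken from the labels as far as they say it; p-values measure the spread between these libraries.

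The deposited counts are whole-number read counts per gene for 21288 genes. Per the submitters' processing notes the tools were bcl2fastq 2.17.1.14, cutadapt, STAR 2.4.2a0, HTSeq 0.6.1p1 and DESeq2 1.10.1, and the genome build was GRCm38. The annotation release and strand setting are not given in the sources used here. The deposited normalized signal is the counts divided by 1 size factor per library, by the authors; these factors differed from DESeq2 size factors recomputed from the counts by at most 2.16e-07 in relative terms. Tests used the counts. Every listed gene had a count of at least 6 in some library. Gene symbols, positions and exon lengths came from GENCODE M21 on GRCm38; 21252 genes matched a symbol and 36 did not. The exon length of a gene is that of all its annotated exons merged. Without a stated strand setting, overlapping and antisense genes, near-identical copies and pseudogenes are uncertain.

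Total counts ran from 12565448 to 21585680 per library. At the filter used, 19010 genes were tested. Naive libraries held 18634506 to 21585680 counts, 7 d libraries 12565448 to 14157742 and 2.5-month libraries 15501075 to 19283086, so depth differed with time after injury.

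Differential expression was tested with edgeR 4.0.16 in R 4.3.3: trimmed-mean scaling, filterByExpr by group (minimum count 10, minimum total 15), robust dispersion estimates and the quasi-likelihood F test, in 1 fit with 1 mean per group and 12 residual degrees of freedom. Adjusted p is Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given ± the standard error (SE) from the F statistic. The lone WT library at 2.5 months borrows its spread from the other groups. CPM values are the deposited counts divided by the scaled library size, from the cpm function of edgeR.

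Before the data were examined, 41 gene lists with 720 members were fixed, of which 699 were tested. Each list was tested with fry of limma 3.58.1 on voom values, adjusted over the 41 lists within a comparison; fry asks whether members move, on balance, one way. Camera, with a preset correlation of 0.01 or an estimated correlation, was the alternative. It asks whether members move more than the other genes, which is a different question from that of fry. Adjusted p given with an estimated correlation are from camera. Across the 11 comparisons, 28 list tests passed with fry, 164 with the preset correlation and 0 with the estimated correlation. Counts of list members are given over all genes and adjusted over the list alone.

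The genes named were chosen by a rule written before the data were examined. In every comparison it takes Kpna4, Fos and called members of the importin family. It takes the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM in a compared group, with ranges of the groups that do not overlap and a symbol that is not a predicted model; the range condition was not asked of interactions, the mean genotype contrast or comparisons with the lone WT library. From each list with 3 or more called members it takes up to 4 with the smallest adjusted p. For interactions and comparisons with fewer than 5 calls it takes called genes up to 10, then the smallest unadjusted p up to 5 in all. The text names a part of these, and says where a gene was named after its values were seen.

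The edgeR and fry steps were tested on simulated counts drawn from the means, dispersions and library sizes of the real genes, with 200 genes changed by known folds. For naive KO against naive WT, with 17945 genes in the fit, 16.4% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 9 calls on unchanged genes. For KO against WT at 7 d, with 18000 genes, the shares were 22.4%, 61.2% and 98.5%. For 7 d against naive in KO, with 17975 genes, they were 26.9%, 67.2% and 97.0%. For the lone WT library against naive WT, with 17980 genes, they were 5.97%, 34.3% and 78.8%. A list of 20 genes shifted 1.5-fold gave a fry p of 4.21e-07 or less in each of these simulations. Each gene was drawn independently of the others, with no trend shared by many genes of a library. The simulations therefore do not show how fry or the recovery of genes fares where genes move together, as in real libraries.

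Alternatives were other size factors, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, fitting only the groups compared and leaving out each library in turn. 3 further alternatives were chosen after seeing the data: a gene-length correction, thinning to the shallowest library, and leaving out the naive KO libraries ko_39 and ko_40 and the 7 d KO library ko_422_7d together. A planned sex covariate was not fitted, because all 18 libraries had the expression of male animals. No pair of libraries within a group was identical.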

Results

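RNA was sequenced from dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of WT mice and of mice without importin alpha3 (KO), a carrier of proteins into the nucleus. The libraries fell into 6 groups: naive WT (n = 4), naive KO (n = 4), SNI 7 d WT (n = 3), SNI 7 d KO (n = 3), SNI 2.5 months WT (n = 1) and SNI 2.5 months KO (n = 3). Single libraries are named by their titles, such as ko_39 for a naive KO library. Total counts per library ran from 12565448 to 21585680. The first principal component of the 2000 most variable genes held 32.2% of the variance. Naive libraries lay between -34.9 and -16.1 on it, 7 d libraries between 19.5 and 44, and 2.5-month libraries between 2.10 and 13.9.

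Kpna4, the gene of importin alpha3 (ENSMUSG00000027782, chromosome 3, 69067149 to 69127113, minus strand, GRCm38), was low in every library labelled KO. Its mean was 2.29 ± 0.489 CPM (SD, n = 4) in naive KO and 121 ± 11.5 CPM (SD, n = 4) in naive WT, or 1.88% of WT. At 7 d it was 2.89 ± 0.606 CPM (SD, n = 3) in KO and 120 ± 4.22 CPM (SD, n = 3) in WT, or 2.41%. At 2.5 months it was 2.68 ± 2.57 CPM (SD, n = 3) in KO and 89.6 CPM in the lone WT library, or 2.99%. Kpna4 counts were 40 to 54, 31 to 45 and 19 to 94 in the KO libraries of these times. Kpna4 fell by 5.73 ± 0.34 on the log2 scale in naive KO (SE, adjusted p = 3.56e-08), by 5.38 ± 0.39 at 7 d (adjusted p = 2.14e-06) and by 5.08 ± 0.43 at 2.5 months (adjusted p = 2.29e-05). Fos, the gene of the transcription factor cFOS, differed between genotypes by -0.02 ± 0.31 on the log2 scale in naive mice, 0.09 ± 0.36 at 7 d and 0.04 ± 0.49 at 2.5 months, all within 1 SE of 0. Of the 21 importin family genes tested, Kpna4 was called in naive mice and the other 20 were not.

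**Figure D1:**
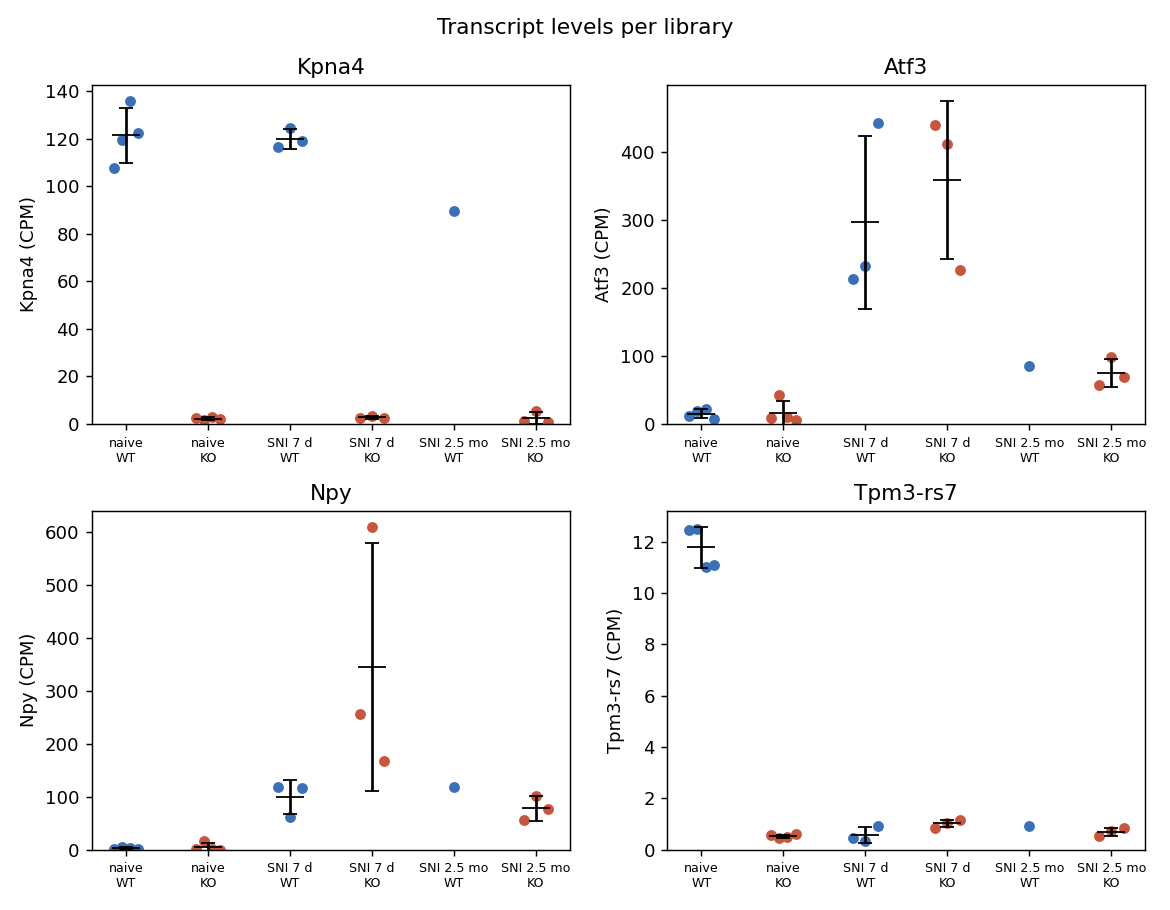
Level of Kpna4, Atf3, Npy and Tpm3-rs7 in CPM (vertical axes, linear) in each of the 18 libraries, by group (horizontal axes), with WT in blue and KO in red. Black bars are the mean and SD where n is above 1. Kpna4 separated the genotypes at every time, and Tpm3-rs7 stood at 11.8 CPM in naive WT and at most 1.02 CPM on average in other groups.

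In naive ganglia, the comparison of KO with WT asks what the loss of importin alpha3 changes without injury. Tpm3-rs7, a tropomyosin 3 related sequence on chromosome 14, fell by 4.46 ± 0.24 on the log2 scale in KO (adjusted p = 1.17e-08). Mab21l1, a developmental regulator, fell by 1.46 ± 0.19 (adjusted p = 0.00191), from 10.8 ± 1.78 CPM in WT to 3.92 ± 0.672 CPM in KO (SD, n = 4 each). The transcript 1500004A13Rik stood at 76.6 ± 6.68 CPM in KO and 39 ± 2.96 CPM in WT, and Gm37558 at 1.17 ± 0.288 and 0.0133 ± 0.0266 CPM; both were named after their values were seen. Gm37558 (chromosome 3, 69119742 to 69122724, minus strand) is a gene model within the span of Kpna4 that shares 0 bases with its exons. Its reads cannot be separated from those of an unspliced transcript of the Kpna4 locus in KO. Unspliced transcript of the intact gene is argued against, since naive WT held 121 CPM of Kpna4. Gm37558 was also low in WT at 7 d, at 0.0513 CPM against 0.885 CPM in KO. Tpm3-rs7 counts are uncertain, since Tpm3 is a near-identical gene, and Tpm3, which was not called, was higher in naive KO by 13.7 ± 2.97 CPM (SE) while Tpm3-rs7 was lower by 11.2 CPM. With Kpna4, these made up the 5 genes called by edgeR among 19010, 2 higher and 3 lower in KO. An unadjusted p under 0.05 was found for 516 genes (2.71%), fewer than the about 5% that chance gives, and DESeq2 called 15. A fit of the compared groups alone called 8 and the gene-length correction 9. Mab21l1, Tpm3 and 1500004A13Rik lie on chromosome 3, as Kpna4 does; without the called genes, 5.65% of genes within 30 Mb of Kpna4 had an unadjusted p under 0.05 against 2.61% elsewhere, and at 7 d 11.9% against 8.34%. None of the 41 lists passed fry. Interferon-stimulated genes had a median log2 difference of -0.35, with 0 of 27 called over all genes (5 lower adjusted over the list alone, fry adjusted p = 0.337).

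At 7 d after SNI, Kpna4 was the gene that differed between KO and WT by edgeR at an adjusted p under 0.05. The next smallest p belonged to Ctla2a, at 2.21 ± 0.37 on the log2 scale (adjusted p = 0.140), and to Prkcb, the gene of protein kinase C beta, at -0.70 ± 0.12 (adjusted p = 0.167). Tef, a clock-controlled transcription factor, was at -0.48 ± 0.09 (adjusted p = 0.293). None of these passed, and no list passed fry. Beside the 1 call, 1604 genes (8.44%) had an unadjusted p under 0.05 and DESeq2 called 20. Leaving out wt_416_7d gave 9 calls and leaving out ko_426_7d gave 2.

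Over naive and 7 d mice together, the mean difference between KO and WT was called for 8 genes, 3 higher and 5 lower in KO. Prkcb fell by 0.56 ± 0.08 on the log2 scale (adjusted p = 0.0133), and Nell2, which encodes a secreted neuronal glycoprotein, fell by 0.57 ± 0.10 (adjusted p = 0.0373). Zfp180, a zinc finger gene, was higher by 0.41 ± 0.07 (adjusted p = 0.0326) and Fam163a by 0.88 ± 0.15 (adjusted p = 0.0428). Kpna4, Tpm3-rs7, Mab21l1 and Gm37558 were the others, and Gm37558 was named after its values were seen. For Tpm3-rs7 this mean joins opposite signs: it was lower in naive KO, but at 7 d it stood at 1.02 ± 0.154 CPM in KO and 0.574 ± 0.306 CPM in WT (SD, n = 3 each). At an unadjusted p under 0.05 there were 1379 genes (7.25%). DESeq2 called 48, a fit of the compared groups alone 3, and the fit without ko_39, ko_40 and ko_422_7d 5. The count was 3 without ko_420__7d, 3 without wt_410_7d, 4 without wt_409_7d, 5 without ko_95, wt_44 or wt_67, 13 without ko_426_7d and 15 without wt_416_7d; Prkcb, Nell2, Zfp180 and Fam163a each lost their call without ko_420__7d, wt_409_7d or wt_410_7d, and Mab21l1 without ko_420__7d or wt_410_7d. Of the 7 genes named by the rule, calls also ended without ko_39, ko_95, wt_28, wt_44 or wt_67 (3 each), ko_35, wt_48 or ko_422_7d (2 each), and ko_40 or wt_416_7d (1 each).

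SNI in WT ganglia, compared with naive WT, raised genes that axon injury is known to switch on in sensory neurons. Sprr1a, a cornified envelope protein linked to axon growth, rose by 6.32 ± 1.32 on the log2 scale, to 957 ± 518 CPM (SD, n = 3). Atf3, a stress-induced transcription factor, rose by 4.26 ± 0.62, from 15.5 ± 7.02 to 297 ± 128 CPM. Csf1, a macrophage growth factor, rose by 2.29 ± 0.24, Cckbr, a cholecystokinin receptor, by 4.87 ± 0.56, and Sema6a, a semaphorin, by 2.82 ± 0.25. Of 39 nerve injury and regeneration genes 27 rose and 0 fell (30 higher adjusted over the list alone, fry adjusted p = 0.000695, adjusted p = 0.112 with an estimated correlation). Fgf3, a fibroblast growth factor, rose from 0.416 ± 0.221 to 18.3 ± 9.26 CPM, and Hmx3, a homeobox gene with 0 counts in naive WT, stood at 1.07 ± 0.481 CPM at 7 d.

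Among stress response genes in WT at 7 d, Chac1 rose by 1.93 ± 0.19 on the log2 scale, Atf5 by 0.91 ± 0.14 and Sesn2 by 1.09 ± 0.19. Of 22 unfolded protein and integrated stress response genes 8 rose (10 higher adjusted over the list alone, fry adjusted p = 0.00245, adjusted p = 0.186 with an estimated correlation). Of 19 AP-1 and Maf transcription factors 4 rose, namely Jun at 1.1 ± 0.15, Atf3, Fosl2 at 1.32 ± 0.29 and Fosl1 at 1.15 ± 0.29 (4 higher adjusted over the list alone, fry adjusted p = 0.0189, adjusted p = 0.242 with an estimated correlation). Fos was at 0.20 ± 0.34 and was not called. Replication-dependent histone genes had 1 of 7 members higher (4 higher adjusted over the list alone, fry adjusted p = 0.0101, adjusted p = 0.186 with an estimated correlation). The complement genes C1qb and C1qc and the receptor Trem2, all expressed by macrophages, rose by 1.89 ± 0.43, 2.04 ± 0.49 and 1.52 ± 0.35, but the macrophage list, with 4 of 26 members called, did not pass (11 higher and 2 lower adjusted over the list alone, fry adjusted p = 0.342). The neutrophil genes Cxcr2 and Ltf fell by 4.27 ± 0.92 and 3.73 ± 0.82, and that list, with 4 of 13 called, did not pass either (11 lower adjusted over the list alone, fry adjusted p = 0.0900). Red blood cell genes, which also mark blood in the tissue, had a mean log2 score of -0.938 ± 1.04 in 7 d WT and 0.417 ± 0.931 in naive WT (SD), with 0 of 9 called (3 lower adjusted over the list alone, fry adjusted p = 0.342).

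In all, 604 genes were called in WT at 7 d, 476 higher and 128 lower. Of 36 calls of named genes, 18 ended without wt_416_7d, 11 without wt_28, 10 without wt_67, 7 without wt_44, 5 without wt_48 or wt_410_7d and 4 without wt_409_7d. The count was 220 without wt_416_7d, 335 without wt_67, 358 without wt_28 and 387 without wt_44. It was 968 without ko_39, ko_40 and ko_422_7d, which enter through the shared spread, and 1111 with DESeq2.

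In KO ganglia at 7 d, compared with naive KO, Npy, the gene of neuropeptide Y, rose by 6.15 ± 0.93 on the log2 scale, to 345 ± 234 CPM (SD, n = 3), Ucn, the gene of urocortin, by 5.99 ± 0.76, and Sprr1b by 7.55 ± 1.13. Of 39 nerve injury genes 34 rose and 0 fell (35 higher adjusted over the list alone, fry adjusted p = 3.18e-05, adjusted p = 0.131 with an estimated correlation), including Sema6a at 3.04 ± 0.25, Stmn4 at 2.94 ± 0.28 and Tnfrsf12a at 1.89 ± 0.19. Slc22a6 and Slc22a8, both organic anion transporters, were lower, at -3.87 ± 1.19 and -3.82 ± 1.06.

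Of 26 macrophage genes 13 rose in KO at 7 d (18 higher and 2 lower adjusted over the list alone, fry adjusted p = 0.0302, adjusted p = 0.60 with an estimated correlation), with Trem2 at 2.42 ± 0.33 and Ctss, a lysosomal protease, at 2.23 ± 0.43. Of 30 potassium channel genes 10 fell and 3 rose (3 higher and 15 lower adjusted over the list alone, fry adjusted p = 0.0442, adjusted p = 0.60 with an estimated correlation), with Kcna2 at -0.63 ± 0.14, Kcns1 at -0.81 ± 0.18 and Kcnmb4 at 1.05 ± 0.19. The mean log2 score of potassium channel genes was -0.299 in ko_420__7d, -0.579 in ko_422_7d and 0.0266 in ko_426_7d, against 0.0417 to 0.226 in naive KO. That of macrophage genes was 0.761, 1.32 and 0.119 in the same libraries, against -1.13 to 0.431. Of 22 stress response genes 12 rose (15 higher adjusted over the list alone, fry adjusted p = 0.000458, adjusted p = 0.239 with an estimated correlation), with Chac1 at 2.04 ± 0.19 and Trib3 at 1.38 ± 0.19. Of 19 AP-1 and Maf factors 4 rose (5 higher adjusted over the list alone, fry adjusted p = 0.00272, adjusted p = 0.338 with an estimated correlation), with Fosl1 at 2.12 ± 0.28, while Fos was at 0.32 ± 0.34 and was not called. Repair Schwann cell genes had 3 of 14 higher (5 higher adjusted over the list alone, fry adjusted p = 0.0302, adjusted p = 0.60 with an estimated correlation), led by Ucn2 at 2.85 ± 0.64, and this list did not pass with the gene-length correction (adjusted p = 0.0554). Histone genes had 3 of 7 higher (5 higher adjusted over the list alone, fry adjusted p = 0.000927, adjusted p = 0.239 with an estimated correlation), with Hist1h4d at 2.14 ± 0.51.

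In all, 2566 genes were called in KO at 7 d, 1447 higher and 1119 lower. The count was 1628 without ko_35, 1700 without ko_39, 1279 without ko_39, ko_40 and ko_422_7d, and 886 in a fit of the compared groups alone. Of 88 calls of named genes, 38 ended without ko_422_7d, 26 without ko_95, 25 without ko_420__7d, 20 without ko_39, 19 without ko_35, 11 without ko_40 and 10 without ko_426_7d. In naive ko_39, 51 genes that SNI raised stood at a median of 7.30% of the way from the other naive KO libraries to the 7 d KO mean, and in naive ko_40 the mitochondrial share was 12.3% of counts. The 7 d KO library ko_422_7d differed in its gene length trend, measured across genes on log2 levels relative to each gene's mean over all libraries. These changed by -0.89 for each 10 times in exon length, against 0.37 and 0.42 in the other 7 d KO libraries.

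Set side by side, the 7 d responses of WT and KO had a Pearson r of 0.630 and a Spearman rho of 0.581 across 19010 genes, which are not independent replicates. Among the 604 genes called in WT, 98.8% moved the same way in KO, with a median ratio of KO to WT log2 change of 1.08. Among the 2566 called in KO the ratio was 1.64, and each selection favours the genotype it was made in. Both genotypes called 434 of the same genes higher and 92 lower, where independent lists of these lengths would share 36.2 and 7.53.

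**Figure D2:**
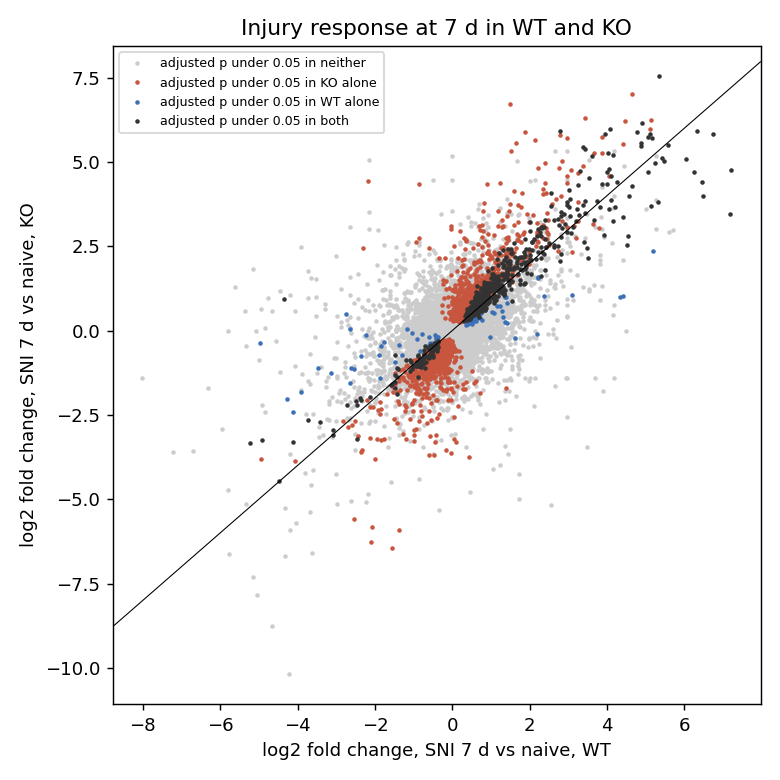
Log2 fold change of SNI 7 d against naive in WT (horizontal axis) and in KO (vertical axis), 1 point per gene for 19010 genes, coloured by whether the adjusted p was under 0.05 in WT, KO, both or neither. The line marks equal change. The r was 0.630 over all genes and 0.942 over the 527 called in both, a selection that favours like changes.

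The interaction asks whether the injury response differed between genotypes, and at 7 d it was called for 2 genes. These were Tpm3-rs7 at 5.30 ± 0.40 on the log2 scale (adjusted p = 3.29e-06) and 1500004A13Rik at -1.16 ± 0.15 (adjusted p = 0.00580). For both, naive WT stood apart from the other groups: 1500004A13Rik was at 76.2 ± 4.39 CPM in 7 d WT and 66.8 ± 3.50 CPM in 7 d KO (SD, n = 3 each). Agbl2, with the next smallest p, was at -3.10 ± 0.68 (adjusted p = 0.948), Kpna4 at 0.36 ± 0.49 and Fos at 0.11 ± 0.48. No list passed fry. At an unadjusted p under 0.05 there were 704 genes (3.70%, where chance gives about 5%), and DESeq2 called 2. The larger count of calls in KO than in WT at 7 d is therefore not shown to be a larger response. The call of 1500004A13Rik ended with the gene-length correction and without ko_39, ko_40 and ko_422_7d, which left 1 gene each.

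At 2.5 months after SNI in KO, compared with naive KO, Nts, the gene of neurotensin, rose by 3.82 ± 0.43 on the log2 scale, Cckbr by 3.28 ± 0.56 and Npy by 4.01 ± 0.86. Of 39 nerve injury genes 14 rose (17 higher adjusted over the list alone, fry adjusted p = 0.0338, adjusted p = 0.519 with an estimated correlation). En1, a homeobox gene, rose by 6.84 ± 0.59, to 3.57 ± 0.908 CPM (SD, n = 3), and Slc30a3, a zinc transporter of synaptic vesicles, by 5.42 ± 0.68, to 1.84 ± 0.338 CPM. Of 16 opioid, cannabinoid and GABA receptor genes 5 fell and 0 rose (7 lower adjusted over the list alone, fry adjusted p = 0.0331, adjusted p = 0.519 with an estimated correlation), with Oprd1, the delta opioid receptor, at -1.56 ± 0.31 and Oprm1, the mu opioid receptor, at -1.91 ± 0.47. Of 9 pruriceptor genes, markers of itch neurons, 3 rose (3 higher adjusted over the list alone, fry adjusted p = 0.0331, adjusted p = 0.526 with an estimated correlation), namely Nts, Nppb at 1.03 ± 0.23 and Sst at 1.13 ± 0.30. The importin family gene Kpna6 fell by 0.52 ± 0.15. With the gene-length correction the lists of nerve injury (adjusted p = 0.128), opioid, cannabinoid and GABA receptor (0.149) and pruriceptor genes (0.539) did not pass fry. The calls of Nppb (0.17 ± 0.24, adjusted p = 0.685), Sst (0.24 ± 0.32, adjusted p = 0.681) and Kpna6 (-0.36 ± 0.11, adjusted p = 0.0573) also ended there, as their log2 changes shrank.

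At 2.5 months in KO, Fos rose by 1.16 ± 0.33 on the log2 scale, from 5.21 ± 1.76 to 11.7 ± 6.42 CPM. The call ended without ko_362_2_5_m, where the change fell to 0.61, adjusted p = 0.175. It also ended without ko_35 (0.96, adjusted p = 0.0797) and with the gene-length correction (0.93 ± 0.34, adjusted p = 0.0959), and, with no smaller change, without ko_39 (1.17, adjusted p = 0.0729), ko_95 (1.21, adjusted p = 0.0530) or ko_367_2_5_m (1.36, adjusted p = 0.0724). Of 23 immediate-early genes 4 rose (13 higher adjusted over the list alone, fry adjusted p = 0.0331, adjusted p = 0.440 with an estimated correlation), among them Ier2 at 1.24 ± 0.29. The mean log2 score of this list was 1.06 in ko_362_2_5_m, 0.168 in ko_367_2_5_m and 0.196 in ko_378_2_5_m, and the highest in naive KO was 0.159, in ko_40. AP-1 and Maf factors had 5 of 19 higher (8 higher adjusted over the list alone, fry adjusted p = 0.0197, adjusted p = 0.440 with an estimated correlation), such as Maff at 0.85 ± 0.20. Glucocorticoid-responsive genes had 6 of 13 higher (7 higher adjusted over the list alone, fry adjusted p = 0.0186, adjusted p = 0.440 with an estimated correlation), with the metallothionein Mt2 at 2.39 ± 0.45. Circadian clock genes had 6 of 16 higher and 2 lower (8 higher and 2 lower adjusted over the list alone, fry adjusted p = 0.0202, adjusted p = 0.440 with an estimated correlation), with Per1 at 1.02 ± 0.22 and Arntl at -1.68 ± 0.36. The labels used here give no time of day of collection, on which clock genes depend, so it cannot be separated from time after injury. Stress response genes had 7 of 22 higher (7 higher adjusted over the list alone, fry adjusted p = 0.0186, adjusted p = 0.440 with an estimated correlation), with Ddit3 at 1.02 ± 0.20. Neutrophil genes had 6 of 13 lower (13 lower adjusted over the list alone, fry adjusted p = 0.0307, adjusted p = 0.440 with an estimated correlation), with the protease Mmp9 at -3.56 ± 0.74. Red blood cell genes had a mean log2 score of -0.209 ± 0.485 against 0.676 ± 0.877 in naive KO (SD), with 1 of 9 lower (3 lower adjusted over the list alone, fry adjusted p = 0.511). Repair Schwann cell genes passed with 0 of 14 called (0 adjusted over the list alone, fry adjusted p = 0.0258, adjusted p = 0.440 with an estimated correlation), and the list of X-inactivation and Y-linked genes had 1 of 4 lower (2 lower adjusted over the list alone, fry adjusted p = 0.0240, adjusted p = 0.440 with an estimated correlation), Kdm5d, a Y-linked histone demethylase gene, at -0.67 ± 0.16.

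Cytoplasmic ribosomal protein genes had 19 of 23 members higher in KO at 2.5 months (21 higher adjusted over the list alone, fry adjusted p = 0.0186, adjusted p = 0.440 with an estimated correlation), with Rps14 at 1.66 ± 0.32 and Rpl7 at 0.80 ± 0.15. Oxidative phosphorylation genes had 10 of 22 higher (13 higher adjusted over the list alone, fry adjusted p = 0.0395, adjusted p = 0.526 with an estimated correlation), with Ndufa2 at 1.36 ± 0.29. Relative to the mean of all libraries, the 2.5-month libraries favoured short genes. Their log2 levels on that scale changed by -0.41, -0.66 and -0.59 for each 10 times in exon length, against 0.12 to 0.33 in naive KO. The mean log2 score of ribosomal protein genes was 0.652 to 0.699 in these libraries. It was 0.864 in ko_422_7d, a 7 d library that also favoured short genes, and -0.332 and -0.369 in ko_420__7d and ko_426_7d; for oxidative phosphorylation genes it was 0.494, -0.322 and -0.375 in these 7 d libraries. With the gene-length correction, the lists that passed fry in KO at 2.5 months were those of circadian (adjusted p = 0.00675), ribosomal protein (adjusted p = 0.00864), neutrophil (adjusted p = 0.0229) and glucocorticoid-responsive genes (adjusted p = 0.0329). Besides those named above, the lists that no longer passed were those of AP-1 and Maf factors (adjusted p = 0.0502), immediate-early (0.191), stress response (0.191), repair Schwann cell (0.237), oxidative phosphorylation (0.191) and X-inactivation and Y-linked genes (0.128). The calls of Ier2 (0.77 ± 0.27, adjusted p = 0.0883) and Maff (0.66 ± 0.21, adjusted p = 0.0614) ended too, among 28 of 79 calls of named genes.

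In all, 2196 genes were called in KO at 2.5 months, 1328 higher and 868 lower, and this count moved with single libraries. It was 14 without ko_367_2_5_m, 458 without ko_378_2_5_m, 366 without ko_39, 385 without ko_35 and 1396 without ko_95. Of 79 calls of named genes, 71 ended without ko_367_2_5_m, 41 without ko_35, 39 without ko_39, 38 without ko_378_2_5_m, 19 without ko_362_2_5_m, 16 without ko_95 and 12 without ko_40, while En1, Ucn, Nts, Slc30a3, Trem2 and Fabp7 were among those called without ko_367_2_5_m. The count was 1186 with the gene-length correction, 3602 with DESeq2 and 4097 in a fit of the compared groups alone.

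**Figure D3:**
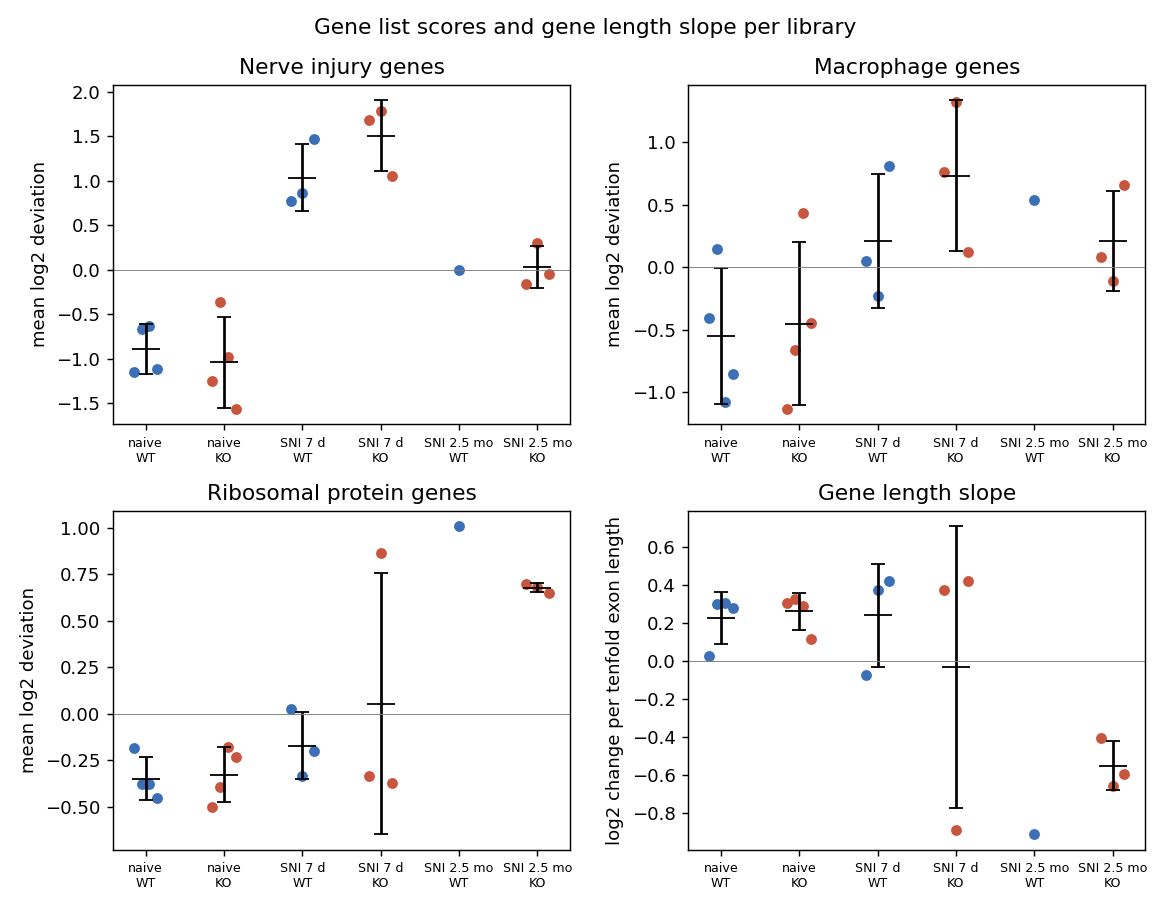
Mean log2 deviation from the mean of all libraries for nerve injury, macrophage and ribosomal protein genes, and the change of that deviation across genes for each 10 times in exon length (vertical axes), per library and group (horizontal axes), with WT in blue and KO in red. Bars are the mean and SD where n is above 1. The length trend was lowest in wt_376_2_5_m, at -0.91, and in ko_422_7d, at -0.89.

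Between 7 d and 2.5 months in KO, injury genes came down. Csf1 fell by 2.45 ± 0.26 on the log2 scale, Sema6a fell by 2.25 ± 0.27, and Crh, the gene of corticotropin-releasing hormone, fell from 18.8 ± 8.40 to 0.597 ± 0.493 CPM (SD, n = 3 each). Of 39 nerve injury genes 24 were lower and 0 higher (31 lower adjusted over the list alone, fry adjusted p = 0.00446, adjusted p = 0.443 with an estimated correlation). Circadian clock genes had 7 of 16 higher and 2 lower (9 higher and 3 lower adjusted over the list alone, fry adjusted p = 0.00513, adjusted p = 0.443 with an estimated correlation), with Dbp at 2.15 ± 0.41 and Arntl at -1.60 ± 0.38, again without a known time of day. Histone genes had 2 of 7 lower (4 lower adjusted over the list alone, fry adjusted p = 0.0249, adjusted p = 0.555 with an estimated correlation). The importin family gene Tnpo2 fell by 0.44 ± 0.11. In all, 1231 genes were called, 407 higher and 824 lower. The count was 5131 without ko_422_7d, 361 without ko_420__7d, 748 without ko_362_2_5_m, 600 without ko_367_2_5_m and 490 without ko_378_2_5_m. Of 44 calls of named genes, 19 ended without ko_420__7d, 16 without ko_378_2_5_m, 13 without ko_362_2_5_m, 12 without ko_367_2_5_m, 10 without ko_426_7d and 5 without ko_422_7d. The count was 5059 without ko_39, ko_40 and ko_422_7d, 2049 with DESeq2 and 285 in a fit of the compared groups alone.

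The KO responses at 7 d and 2.5 months had 318 higher and 234 lower genes in common, among them Npy, En1 and Ucn, where independent lists would share 101 and 51.1. Both comparisons use the same naive KO libraries. In 10 simulations of unchanged groups against them, the correlation of log2 changes was 0.379 on average and the covariance 0.0606. At most 1 gene was called in either simulated comparison. The 0 genes shared there therefore cannot show how far shared controls raise the overlap of long lists. The observed correlation was 0.482 and the observed covariance 0.331. With the naive KO libraries split between the comparisons, 3 to 70 genes were shared over 6 splits, where independent lists would share 0.0841 to 20.1. The 2.5-month calls numbered 3 to 573 in these splits, and the covariance was 0.235 to 0.319. Splitting the controls leaves in place a trend towards short genes in some libraries of both times. Log2 levels changed by -0.89 for each 10 times in exon length in ko_422_7d and by -0.41, -0.66 and -0.59 at 2.5 months. They changed by 0.37 and 0.42 in the other 7 d KO libraries. The part of this trend in the overlap was not tested.

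The lone WT library at 2.5 months borrows its spread from the other groups. Against naive WT, the macrophage genes Trem2 and C1qb were higher by 3.16 ± 0.42 and 3.00 ± 0.54 on the log2 scale, with 6 of 26 macrophage genes higher (6 higher adjusted over the list alone, fry adjusted p = 0.186). Antigen presentation genes had 9 of 20 higher (11 higher adjusted over the list alone, fry adjusted p = 0.0906), with B2m at 1.38 ± 0.30. Interferon-stimulated genes had 8 of 27 higher (8 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.0906), with Oasl2 at 1.11 ± 0.14. Ribosomal protein genes had 20 of 23 higher (22 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.0331, adjusted p = 0.805 with an estimated correlation), with Rplp1 at 2.21 ± 0.39. The importin family genes Tnpo3 and Xpo1 fell by 0.84 ± 0.20 and 0.59 ± 0.17. Relative to the mean of all libraries, wt_376_2_5_m favoured short genes. Its log2 levels on that scale changed by -0.91 for each 10 times in exon length, against 0.024 to 0.30 in naive WT. With the gene-length correction 12 ribosomal protein genes were called (fry adjusted p = 0.0313), Rplp1 at 0.69 ± 0.14, and 5 antigen presentation genes. The calls of B2m (0.26 ± 0.27, adjusted p = 0.577) and Xpo1 (-0.33 ± 0.14, adjusted p = 0.156) ended, among 12 of 53 calls of named genes. Fos was at 1.1 ± 0.45 and was not called. In all, 2473 genes were called, 1656 higher and 817 lower. Of 53 calls of named genes, 5 ended without wt_44 or wt_67, 3 without wt_48 and 1 without wt_28. The count was 1566 without wt_44, 1533 without wt_67, 1396 with the gene-length correction, 4139 without ko_39, ko_40 and ko_422_7d, and 5876 in a fit of the compared groups alone.

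Between KO and this WT library at 2.5 months, the interferon-stimulated genes Oasl2 and Usp18 fell by 1.52 ± 0.15 and 2.60 ± 0.43 on the log2 scale (adjusted p = 6.00e-05 and 0.0317). Oasl2 stood at 51.7 ± 2.93 CPM in KO (SD, n = 3), 148 in the WT library and 69.0 ± 6.38 in naive WT. Cyp26a1, which degrades retinoic acid, fell by 3.10 ± 0.51, and Lrch2 was higher by 3.26 ± 0.49, at 0.628 CPM in the WT library and 6.06 ± 1.88 in KO. Of 27 interferon-stimulated genes 2 were lower (9 lower adjusted over the list alone, fry adjusted p = 0.175), and no list passed fry. In all, 9 genes were called, 2 higher and 7 lower in KO, beside 2334 at an unadjusted p under 0.05 and 151 with DESeq2. The count was 3, 3 and 4 without ko_362_2_5_m, ko_367_2_5_m and ko_378_2_5_m in turn, each of which ended the calls of Usp18 and Cyp26a1. It was 17 with the gene-length correction, 70 without ko_39, ko_40 and ko_422_7d, and 5 in a fit of the compared groups alone, where Kpna4 itself was not called.

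The interaction at 2.5 months was called for 4 genes: Tpm3-rs7 at 4.09 ± 0.51 on the log2 scale, Lrch2 at 3.37 ± 0.53, 1500004A13Rik at -1.19 ± 0.19 and 4930556M19Rik at 4.21 ± 0.67, whose call ended with the gene-length correction (4.17 ± 0.74, adjusted p = 0.113). Kpna4 was at 0.65 ± 0.57 and Fos at 0.06 ± 0.58. At an unadjusted p under 0.05 there were 1612 genes, DESeq2 called 43, and no list passed fry. Leaving out ko_35, ko_39, ko_40, ko_95, wt_28, wt_44, wt_48, wt_67, ko_367_2_5_m or ko_378_2_5_m left 1 call, as did thinning and a fit of the compared groups alone, and 0 were left without ko_39, ko_40 and ko_422_7d.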

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

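The tests of reads shared with Tpm3 and of the gap kept after injury, both tests of injury transcripts in ko_39 and the splits without Kpna4 and Gm37558 were chosen after the result was seen. Library measures, list scores and genes gave 106 sets of 4 values, each from naive WT or naive KO. The highest or lowest library stood apart in 7 sets, where chance gives about 5% of independent sets. These sets share the same libraries and are not independent.

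The interaction was called for 2 genes at 7 d and 4 at 2.5 months, where WT has 1 library. Tpm3-rs7 and 1500004A13Rik were called both times, with naive WT apart from the other groups, but both interactions use the same naive libraries. Tpm3, which was not called (0.50 ± 0.11, adjusted p = 0.459), was higher in naive KO by 1.22 times the CPM that Tpm3-rs7 lost, which is consistent with reads passing between these near-identical genes. A variant of steady effect linked to Kpna4 would keep WT and KO apart after injury, if naive and 7 d mice of a genotype carried it alike. Besides Kpna4 and Gm37558, 3 genes were called between naive mice. In the 7 d libraries Tpm3-rs7 kept -0.0400 ± 0.0177, 1500004A13Rik -0.249 ± 0.0895 and Mab21l1 0.227 ± 0.151 (SE) times the naive gap in CPM. This argues against a variant so carried for the first 2. These were noticed because naive WT alone stood apart, which lessens what the test can show. The test planned for such a variant met its bound: without the genes called in each comparison, the share of genes with a p under 0.05 within 30 Mb of Kpna4 was 2.2 times that elsewhere between naive KO and WT (exact p = 0.00954, one-sided, over all windows of as many genes), 1.43 times at 7 d (exact p = 0.0169) and 1.18 times for the 7 d interaction (exact p = 0.295), so a linked variant stays open for Mab21l1 and other nearby genes, as do, untested, an effect of importin alpha3 and another origin of the naive WT mice.

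Naive library ko_39 carried injury transcripts: over 51 genes that SNI raised, it stood at a median of 7.30% of the way from the other naive KO libraries to the 7 d KO mean. A mislabelled injured sample is argued against by that level. The lower quartile of 5.26% was 0.528 times the upper of 9.97%, and 48 genes were above the mean of the other naive KO libraries. This is consistent with a small admixture of injured KO tissue, though the ratio lay close to the bound set for it. A minor injury of that animal would look alike and was not tested. Naive WT libraries were not scored on these genes. Their mean log2 scores for the nerve injury list ran from -1.15 to -0.631. The score was -0.361 in ko_39 and -1.56 to -0.982 in the other naive KO libraries.

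The mitochondrial share was 12.3% in ko_40, against 3.73% to 4.79% in the other naive KO libraries, and its 20 most abundant genes held 15.9% of counts. In wt_67 the mitochondrial share was 3.49% and the satellite glia score -0.216. The gene length slope of wt_28 was 0.0245, below 0.278 in the nearest other naive WT library. The stress response score of wt_48 was -0.121, and Zfp180 stood at 86.2 CPM in ko_35.

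Whether other splits of the same libraries gave as many genes was counted. For naive KO against WT, 1 of 35 splits gave as many as 5, the real one, with 3 as the highest other. These 5 include Kpna4 and Gm37558, which lies in its span, and without them 2 of 35 splits gave as many as 3, with 3 the highest other, so chance could not be excluded for that number of genes. The real split alone gave as many genes for 7 d against naive in WT (604 genes, 1 of 35 splits, highest other 121) and in KO (2566, 1 of 35, highest other 525). The same held for 2.5 months against naive in KO (2196, 1 of 35, highest other 8). A share of 1 in 35 is the smallest these splits can give, so this argues only weakly against chance. It cannot tell injury from another difference between the sets of libraries. For the mean genotype difference 5 of 100 drawn splits gave as many as 8 genes, with 265 the highest other, and without Kpna4 and Gm37558 5 gave as many as 6, with 265 the highest other. For the 7 d interaction 7 of 100 gave as many as 2, with 274 the highest other, so chance could not be excluded for these numbers of genes. The count of splits weighs how many genes were called, and does not replace the adjusted p of a single gene such as Tpm3-rs7. The 10 splits for KO against WT at 7 d (1 gene, Kpna4, 3 splits with as many, highest other 760) and for 2.5 months against 7 d in KO (1231 genes, 2 splits, highest other 2439) are too few for a share under 0.05. The split with 760 genes set ko_420__7d, ko_426_7d and wt_416_7d against the rest, and that with 2439 set ko_420__7d, ko_426_7d and ko_362_2_5_m against the rest, which points to a structure of the libraries beside genotype and time.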

How the results depend on the processing

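The gene-length correction, thinning to the shallowest library and leaving out ko_39, ko_40 and ko_422_7d were chosen after seeing the data. The planned sex covariate was not run, because all 18 libraries had the expression of male animals. No paired analysis was possible because the groups share no replicate numbers. Leaving out wt_376_2_5_m, the lone library of its group, gives no value. Leaving out a library also leaves fewer residual degrees of freedom; beyond that, the cause was not tested. Thinning to the shallowest library moved 1 count of called genes by over 1.5 times, that of the 2.5-month interaction. With other size factors and with no low-count filter, each count of called genes stayed within 1.5 times.

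With the gene-length correction, 9 genes were called for KO against WT in naive mice, 17 at 2.5 months, 1186 for 2.5 months against naive in KO, 1396 in WT and 1 for the 7 d interaction. Thinning left 1 call for the 2.5-month interaction. Without ko_39, ko_40 and ko_422_7d there were 70 calls for KO against WT at 2.5 months, 5 for the mean difference, 968 for 7 d against naive in WT and 1279 in KO, 4139 for 2.5 months against naive in WT, 5059 for 2.5 months against 7 d in KO, and 1 and 0 for the 7 d and 2.5-month interactions. DESeq2 called 15, 20, 151 and 48 genes for KO against WT in naive, 7 d and 2.5-month mice and on average, 1111 for 7 d against naive in WT, 3602 for 2.5 months against naive in KO, 2049 for 2.5 months against 7 d in KO and 43 for the 2.5-month interaction. Fitting only the groups compared gave 8, 5 and 3 for KO against WT in naive and 2.5-month mice and on average, 886 and 4097 for 7 d and 2.5 months against naive in KO, 5876 for 2.5 months against naive in WT, 285 for 2.5 months against 7 d in KO and 1 for the 2.5-month interaction. Of the list tests, 164 passed with camera at a preset correlation and 0 with camera at an estimated one. The side-by-side correlation was 0.781 with at least 1 CPM in 3 libraries and 0.838 over called genes with a log2 change of at least 1. The genes shared by the KO responses numbered a median of 11 over 6 splits of the controls.

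Leaving out 1 library gave 5 to 6 calls for KO against WT in naive mice, 1 to 9 at 7 d, 3 to 4 at 2.5 months and 3 to 15 on average, 220 to 646 for 7 d against naive in WT and 1628 to 3392 in KO, 14 to 1814 for 2.5 months against naive in KO and 1533 to 2320 in WT, 361 to 5131 for 2.5 months against 7 d in KO, 2 to 2 for the 7 d interaction and 1 to 3 for the 2.5-month interaction.

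Of 5105 alternative values of named genes, 33 changed sign, all of Fos or Kpna4 in comparisons where neither value was called. A further 614 lost their call when 1 library was left out, 70 without ko_39, ko_40 and ko_422_7d, 68 with only the groups compared, 54 with the gene-length correction, 13 with thinning, 11 with no filter, 3 with at least 1 CPM in 3 libraries, 3 with other size factors and 2 with DESeq2. Kpna4 went to 0.0010 on the log2 scale for 7 d against naive in WT with at least 1 CPM in 3 libraries, and to 0.0081 with the gene-length correction and 0.049 without ko_39, ko_40 and ko_422_7d for 2.5 months against 7 d in KO. Fos went to -0.036 for KO against WT at 2.5 months with thinning, and to -0.0030 at 7 d and -0.16 on average without ko_39, ko_40 and ko_422_7d. Leaving out 1 library, Fos ran from -0.20 to 0.18 for KO against WT in naive mice, -0.050 to 0.39 at 7 d, -0.51 to 0.26 at 2.5 months and -0.055 to 0.18 on average, -0.094 to 0.35 for 7 d against naive in WT, -0.089 to 0.41 for the 7 d interaction and -0.49 to 0.28 for the 2.5-month interaction. Kpna4 ran from -0.068 to 0.042 for 7 d against naive in WT, -0.92 to 0.62 for 2.5 months against naive in KO, -1.27 to 0.28 for 2.5 months against 7 d in KO and -0.49 to 1.05 for the 2.5-month interaction.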

Other observations

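The tests of gene length were chosen after the result was seen, as was thinning to the depth of the shallowest library. The comparison with ko_422_7d was added last, with its bound set once its scores were known, and it withdrew an earlier verdict that the correction argued against length as the whole cause for ribosomal protein genes. In KO at 7 d, genes of non-peptidergic nociceptors, the C-fibre neurons that lack neuropeptides, had 7 of 17 members lower and 1 higher (1 higher and 13 lower adjusted over the list alone, fry adjusted p = 0.0899), with Agtr1a at -1.13 ± 0.28 and Gfra1 at 1.21 ± 0.20 on the log2 scale. Myelinating Schwann cell genes had 5 of 18 lower (11 lower adjusted over the list alone, fry adjusted p = 0.117), with Mag, a myelin glycoprotein, at -1.08 ± 0.33, and endothelial genes 4 of 15 lower (8 lower adjusted over the list alone, fry adjusted p = 0.0899), with Kdr, a VEGF receptor, at -1.29 ± 0.30. At 2.5 months in KO, satellite glia genes had 4 of 16 lower (6 lower adjusted over the list alone, fry adjusted p = 0.237), with Fabp7 at -1.42 ± 0.22 and Gja1, the gene of connexin 43, at -0.95 ± 0.23, a call that ended with the gene-length correction (-0.67 ± 0.21, adjusted p = 0.0596). None of these lists passed fry.

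Ribosomal protein genes rose by a median of 1.02 on the log2 scale in KO at 2.5 months, in libraries that favoured short genes. These calls did not need unequal numbers of reads, since 18 of the 19 called genes were called after thinning. Thinning evens out the number of reads alone, so it cannot test a library factor that moves with depth. Genes matched on exon length and level had a median of 0.34, 0.329 times that of the ribosomal protein genes, so length may account for part of the rise. Exon length was taken over all annotated exons of a gene merged, with a median of 1770 bases for ribosomal protein genes. It can exceed the length of the transcript present, so the matching and the correction may remove too little. Length as the whole cause, or another library factor that moves with it, stays open: after the gene-length correction 16 of 23 were called, with a median of 0.53, but the rise left in ko_422_7d over the other 7 d KO libraries was 1.09 times that left at 2.5 months. The same holds for oxidative phosphorylation genes: 6 of 22 were called after the correction, with the median going from 0.74 to 0.16 and a ratio for ko_422_7d of 1.64. RNA quality, a library batch, the time of day or the age of the mice at 2.5 months and time after injury cannot be told apart, because each time has its own libraries. Nor can the surgery be told apart from the nerve injury.

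Trim59, which lies beside Kpna4 on chromosome 3, stood at 3.89 ± 0.980 CPM in naive KO and 2.43 ± 0.443 in naive WT, and at 4.81 ± 0.477 and 2.25 ± 0.403 CPM at 7 d (SD). Its log2 difference was 0.68 ± 0.21 in naive mice and 1.09 ± 0.25 at 7 d, and neither was called. It was named after its values were seen.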
